A study of Mus musculus with 24 samples.

How the data were processed

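RNA sequencing was done on mouse nucleus accumbens, a ventral part of the striatum that takes part in reward and motivation. The labels give 24 libraries in 2 experiments and 8 groups of 3 libraries. In the wild-type experiment, C57BL/6J females and males were either controls or stressed. In the floxed experiment, all mice were stressed and carried a Dnmt3a gene flanked by loxP sites, and received an adeno-associated virus (AAV) that expressed either GFP alone or Cre recombinase, which deletes the flanked part of the gene. The labels state that each library was made from pooled mRNA of 4 mice with an Illumina mRNA kit, so a library is the unit of replication and n counts libraries. The protocol text names dorsal striatum beside nucleus accumbens in the description of the tissue punches. The series title names a subchronic variable stress, a schedule of changing stressors. Its length and the time between the last stressor and tissue collection are not given in the sources used here.

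The deposited table holds raw counts per Ensembl gene, whole numbers with no scaling by the authors, for 37991 genes. The labels list Bowtie2 2.1.0, TopHat2 2.0.9 and HTSeq 0.6.0 and the mouse builds NCBIM37 and mm9, without stating the settings, so it is not known here whether reads were counted by strand, and the count of a gene that overlaps another gene on the opposite strand can hold reads of both. Gene symbols, GC content, transcript length and overlaps were taken from a later annotation (GENCODE M21, build GRCm38), matched by Ensembl ID. A symbol was found for 32919 IDs and not for 5072, which took 0.736% to 0.798% of the counts of a floxed library and 0.753% to 0.911% of a wild-type library. Because the builds differ, no coordinates are given. A total of 6757 genes had 0 counts in all libraries.

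Total counts per library ranged from 28132563 to 59829070 in the floxed experiment and from 7116123 to 12145551 in the wild-type experiment. Mitochondrial genes took 7.06% to 8.89% of the counts in floxed and 4.82% to 7.09% in wild-type libraries. The experiments differ in genotype, virus, depth and any sequencing batch all at the same time, so they were fitted apart and no fold change was computed between them.

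Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Within each experiment, genes were filtered with filterByExpr (15249 genes tested in the wild-type and 17597 in the floxed experiment), scaled with TMM factors and fitted with a robust quasi-likelihood negative binomial model with a mean for each of the 4 groups. Contrasts were tested with the quasi-likelihood F test, and p-values were adjusted with the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p below 0.05. Fold changes are on the log2 scale with their standard error (SE), and expression per library is in CPM (edgeR's counts per unit of library size, scaled with TMM factors), given as mean ± SD over libraries. The contrasts were stressed against control and Cre against GFP in each sex, their mean over the sexes, their difference between the sexes (interaction, female minus male), and female against male within each experiment.

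The named genes follow a rule fixed before the data were examined. For stress and for Cre in each sex it took up to 12 genes per direction with the largest fold change among called genes with a mean log2 CPM of at least 1 and no overlap between the 3 libraries of each group. Where fewer than 10 genes met this, the list was filled to 10 with the genes of smallest p, and these are said not to pass. For averaged contrasts and interactions it took the 5 called genes of smallest p per direction, or the 3 genes of smallest p if none was called. For sex it took Xist, the fixed lists of Y-linked genes and of X-linked genes that escape inactivation, and the other called genes of smallest p. Dnmt3a, Dnmt1, Dnmt3b, Fos, Fkbp5, Drd1, Drd2 and Esr1 were named wherever tested, and up to 4 members of smallest p of each gene list that is described.

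A further 29 gene lists were also fixed before the data were examined. The pathway lists hold the DNA methylation machinery, immediate early genes, glucocorticoid-responsive genes, heat shock and unfolded protein response, interferon and antigen presentation, glutamate receptors and postsynaptic density, GABA signalling, synaptic vesicle release, hormone, neuropeptide and monoamine receptors, and oxidative phosphorylation subunits. The cell type lists hold D1, D2 and shared medium spiny neuron genes and striatal interneuron markers. Lists of other cell types, for RNA from neighbouring tissue, hold cortical and other excitatory neuron, septal, pallidal and hypothalamic, oligodendrocyte, oligodendrocyte precursor, astrocyte, reactive glia, microglia, endothelial, choroid plexus, meningeal and blood genes. Ribosomal protein genes served as a sign of RNA quality, and clustered protocadherins, imprinted genes and germline genes as known targets of DNA methylation. Members without a symbol match or below the filter are not in a list's test, and a list needed at least 4 tested members. Each list was tested on log2 CPM (prior count 2) with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 29 lists of a contrast. Camera asks whether a list's genes moved more than the other genes. It was repeated with the correlation estimated from each list's own residuals, and with fry, which asks only whether a list's genes moved on balance in a single direction. Counts "adjusted over the list alone" apply the Benjamini-Hochberg method to the list's members only. A library's score for a list is the mean deviation of its members' log2 CPM from their mean over the 12 libraries.

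Fold changes of pairs of contrasts were correlated across autosomal genes, with a two-sided exact permutation test that relabels the libraries of both contrasts in all 400 ways (smallest p possible 0.01), and adjusted over the 6 pairs. Overlaps between the sexes used genes at an unadjusted p below 0.05 and a fold of at least 1.3, against the number expected from the list sizes. With 3 libraries against 3, an exact permutation test of a single gene cannot give a p below 0.1.

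Replicate numbers are shared between groups, so it was checked whether they pair libraries. After centring each group, the log2 CPM of same-numbered control and stressed female libraries correlated across genes at 0.592, 0.334 and 0.524, control and stressed male libraries at 0.341, 0.247 and 0.0859, GFP and Cre female libraries at 0.0857, -0.138 and -0.452, and GFP and Cre male libraries at -0.109, 0.0508 and 0.109. Each library's correlations with the libraries of the other groups were also averaged by replicate number. This mean was highest for the library's own number in 7 of 12 wild-type and 3 of 12 floxed libraries. Of the groups compared within a sex, only the wild-type females thus met the preset rule of 0.1 in each pair. Across the sexes, control male and stressed female libraries of the same number also did, at 0.607, 0.39 and 0.231, and the replicate block was tried for all contrasts. Adding the replicate number as a block left the count of genes called for stress in females at 0 and that of lists at 9 against 8.

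The alternatives tried were RLE factors, no filter, DESeq2, limma-voom, the replicate block, a fit of only the 2 groups compared, an unadjusted p with a fold of 1.3, and leaving out each library in turn. Alternatives chosen after seeing the data were a cortical marker score or a choroid plexus score as a covariate, a correction of each library's trend with GC content or with gene length (loess, span 0.3), the GC correction with the replicate block, and thinning the floxed libraries to the lowest total. No scaling moved the median log2 fold change of all genes by more than 0.06. Pairs of libraries of a group were checked for duplicates over genes with at least 20 counts, and in the 24 pairs the chi-squared per degree of freedom was 6.87 to 57.27, so no library was a copy of another of its group. Libraries of different groups were not compared in this way. The fit was tested on simulated data with known folds. It recovered 11.9%, 59.7% and 92.4% of genes changed 1.5-fold, 2-fold and 4-fold at the depth and spread of the male stress comparison (6 false among 115 calls), and 67.2%, 82.1% and 93.9% at those of the male Cre comparison (9 false among 171 calls). The counts were drawn independently for each gene, without any structure that real libraries share, so these shares need not hold in the real data. The lists of differential genes named in the sample descriptions were not used here. Some genes that the naming rule takes in are not reported here.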

Results

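Gene expression was measured by RNA sequencing of mouse nucleus accumbens in 24 libraries, each from the pooled mRNA of 4 mice. The wild-type experiment held control females, control males, stressed females and stressed males, and the floxed experiment held stressed females and males with AAV-GFP or AAV-Cre. Each of these 8 groups had 3 libraries. Total counts per library were 9607537 to 10438442 in control females, 9034244 to 12145551 in control males, 7116123 to 9542124 in stressed females and 9159208 to 10119709 in stressed males. They were 33791802 to 34653592 in GFP females, 29429777 to 38830969 in GFP males, 28132563 to 42249311 in Cre females and 33687785 to 59829070 in Cre males.

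Xist and the main Y-linked genes followed the labelled sex in all 24 libraries. Xist, the RNA that silences an X chromosome in females, stood at 1290 ± 327 CPM in wild-type females against 3.11 ± 3.26 in wild-type males, and at 1570 ± 218 against 6.91 ± 5.11 in the floxed experiment (SD, n = 6 libraries per sex). The Y-linked genes ran the other way: Ddx3y, an RNA helicase, was at 64.5 ± 19 CPM in wild-type males against 0.352 ± 0.265 in females. Kdm5d, Eif2s3y and Uty were also called lower in females in both experiments (adjusted p of at most 3.48e-06, lower in 6 of 6 female libraries). Uba1y was called in the floxed experiment at 0.767 ± 0.139 CPM in males against 0.00954 ± 0.0234 in females, and Usp9y, with 0 counts in all 6 floxed female libraries and 2.21 ± 1.35 CPM in males, did not pass (adjusted p = 0.13). In the wild-type experiment Uba1y did not follow the sex, at 2.68 to 5.07 CPM in females and 2.27 to 5.97 in males. Of the 8 tested X-linked genes that escape inactivation, Eif2s3x (log2 0.57, SE 0.03), Kdm6a (log2 0.43, SE 0.04), Kdm5c (log2 0.29, SE 0.03), Ddx3x (log2 0.32, SE 0.05) and 5530601H04Rik (log2 0.33, SE 0.05) were called higher in floxed females, with adjusted p from 5.38e-06 to 0.0369. In the wild-type experiment none of the 8 passed (Eif2s3x log2 0.51, adjusted p = 0.125).

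Few genes outside these sets differed by sex. G530011O06Rik, which overlaps another gene on the opposite strand, was higher in wild-type females (15.2 ± 1.85 against 8.57 ± 1.35 CPM, n = 6, adjusted p = 0.0284), a call that held only without control male library 3 or stressed female library 1 among the 12 fits that leave out a library (adjusted p up to 0.148). In all, 6 genes differed by sex in wild-type mice (2 higher and 4 lower in females) and 12 in floxed mice (6 and 6) with edgeR, against 13 and 89 with DESeq2. The floxed count was 92 without Cre male library 3 and 7 with a cortical marker score as a covariate, and the wild-type count was 14 with a GC correction. Ddx3x and 5530601H04Rik each lost their call in 9 of 12 fits that leave out a library (adjusted p up to 0.187 and 0.147). The fits that kept it were those without Cre female library 3 or Cre male library 2 or 3 for Ddx3x, and without Cre female library 2, Cre male library 3 or GFP female library 3 for 5530601H04Rik.

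The first question of the series is what stress changes in the nucleus accumbens of each sex. In females, the immediate early genes, which neurons switch on within minutes of activity, were lower after stress as a group. Npas4, an activity-induced transcription factor, stood at 12.1 ± 1.07 CPM in stressed and 26.6 ± 5.34 in control females (SD, n = 3 libraries each), a log2 difference of -1.13 (SE 0.18). Fos stood at 7.8 ± 0.93 against 18.3 ± 2.56 CPM, Arc, a regulator of synaptic receptors, at 51.2 ± 12.7 against 104 ± 41, and Egr2 at 5.52 ± 0.706 against 11.5 ± 2.98. All 23 measured immediate early genes had a negative fold change (median log2 -0.59; camera adjusted p = 4.61e-29, and adjusted p = 0.0217 with an estimated correlation). Of them, 12 were lower when adjusted over the list alone and 0 passed over all genes, with adjusted p of 0.316 for Npas4 and 0.354 for Fos. With the replicate block, which takes the pairing of the female libraries into account, the adjusted p was 0.0797 for Npas4 and 0.141 for Fos.

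Other genes of smallest p in females did not pass either (adjusted p = 1). They were Frem3 (log2 1.5, SE 0.3), the neuroendocrine protein gene Resp18 (log2 0.77, SE 0.16), Npy2r, a neuropeptide Y receptor (23.4 ± 3.81 against 14 ± 2.33 CPM), Clspn (log2 -1.32, SE 0.28), Lef1 (log2 -0.89, SE 0.22) and Nr4a1 (log2 -1, SE 0.27). Resp18 and Lef1 overlap a gene on the opposite strand. The genes named in advance had log2 values of -0.07 for Dnmt3a, 0.03 for Dnmt1, -0.03 for the glucocorticoid-induced Fkbp5, -0.04 for the dopamine receptor Drd1, -0.22 for Drd2 and 0.33 for the oestrogen receptor Esr1, none of which passed.

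Several lists besides the immediate early genes moved in stressed females at the preset correlation, and none of them kept its call with an estimated correlation. Shared medium spiny neuron genes were lower, with 19 of 20 negative (median log2 -0.14, adjusted p = 0.000387, and adjusted p = 0.203 with an estimated correlation; Pde10a -0.27, Rgs9 -0.29). Cortical and other excitatory neuron markers, which mark RNA from outside the striatum, were also lower, with 11 of 15 negative (median log2 -0.46, adjusted p = 3.67e-05, and 0.265 as the adjusted p with an estimated correlation). Among them Slc17a7, the vesicular glutamate transporter of cortical neurons, had log2 -1.62 and Slc30a3 log2 -1.7, and Slc17a7 was at 109 CPM in control female library 2 against 9.89 to 41 in the other wild-type female libraries. Endothelial markers (median log2 -0.16, 14 of 17 negative, adjusted p = 0.00589, and adjusted p = 0.265 with an estimated correlation) and clustered protocadherins, neuronal surface identity proteins (median log2 -0.1, 17 of 24 negative, adjusted p = 0.0124 and 0.357), were lower. Oxidative phosphorylation subunits (median log2 0.11, 67 of 85 positive, adjusted p = 0.000321 and 0.462), imprinted genes (median log2 0.13, 16 of 21 positive, adjusted p = 0.00171 and 0.0679) and ribosomal protein genes (median log2 0.16, 61 of 79 positive, adjusted p = 4.92e-05 and 0.659) were higher. The second p in each case is the adjusted p with an estimated correlation. With the cortical marker score as a covariate the medians were -0.01 for ribosomal protein genes, 0.05 for oxidative phosphorylation subunits, 0.24 for imprinted genes, -0.09 for protocadherins, -0.23 for endothelial markers and -0.27 for shared medium spiny neuron genes. No member of these lists passed over all genes or adjusted over the list alone.

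In total edgeR called 0 genes for stress in females, with 256 at an unadjusted p below 0.05 where chance would give 762, and 808 genes (5.3%) had no overlap between the 3 stressed and 3 control libraries where chance gives 10%. DESeq2 called 2 genes, Npas4 (adjusted p = 0.000175) and Fos (adjusted p = 0.00192), limma-voom 0, and edgeR without a filter 5, all lower. Without control female library 3 edgeR called 1 gene, Npas4 (adjusted p = 0.044, over fits that leave out a library 0.044 to 1). The count of lists was 8 of 29, and 5 without stressed female library 1 or 3.

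In stressed males, Fos fell 3.27-fold, from 21 ± 5.58 to 6.43 ± 0.449 CPM (SD, n = 3 libraries each; log2 -1.71, SE 0.21, adjusted p = 0.022), and was lower in 3 of 3 stressed libraries than in any control. The other immediate early genes lay on the same side, with Btg2, an antiproliferative regulator, at 7.96 ± 0.587 against 16.6 ± 4.07 CPM, Npas4 at 10.5 ± 1.6 against 19.2 ± 1.32 and Arc at 46.4 ± 5.31 against 105 ± 14.2. All 23 had a negative fold change (median log2 -0.57; camera adjusted p = 2.73e-23, and adjusted p = 0.0437 with an estimated correlation). Of them 1 passed over all genes and 12 were lower when adjusted over the list alone. Crh, the corticotropin-releasing hormone gene, had 5.69 ± 0.0681 CPM in stressed against 2.86 ± 0.566 in control males (log2 0.98, SE 0.22). It was the only member of the septal, pallidal and hypothalamic list to pass adjusted over the list alone (adjusted p = 0.00608), not over all genes (adjusted p = 1).

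**Figure D1:**
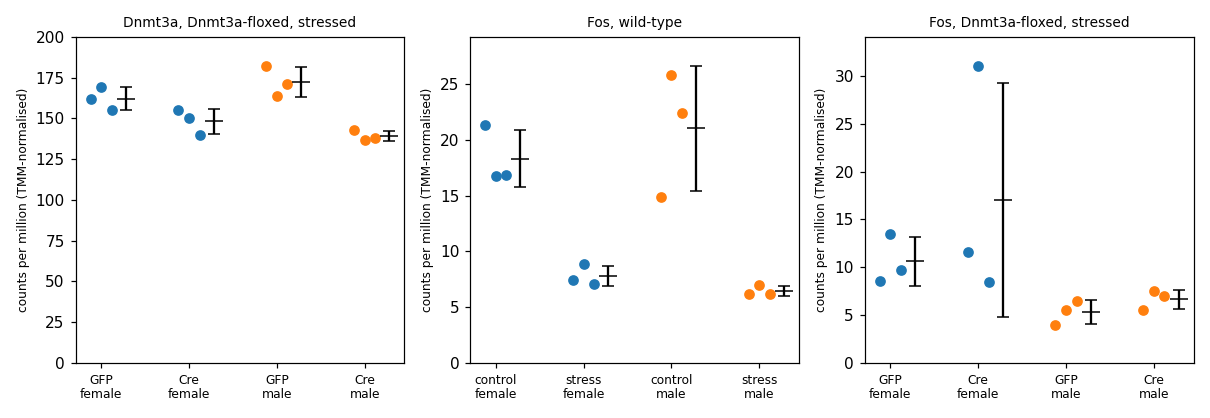
Expression of Dnmt3a in the floxed experiment and of Fos in both experiments, in CPM on the vertical axis, by group. Each point is a library of 4 pooled mice and the bar is the mean ± SD (n = 3); Fos was at 6.43 ± 0.449 CPM in stressed wild-type males against 21 ± 5.58 in controls, and Dnmt3a at 140 ± 2.99 CPM in Cre males against 172 ± 8.63 in GFP males.

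The remaining male genes of smallest p did not pass (adjusted p of at least 0.479). They were Ifit3b, an interferon-induced gene with close paralogs (log2 1.12, SE 0.24), the sulfatase gene Sulf1 (log2 -0.74, SE 0.16), Rasgrf2, a Ras exchange factor (log2 0.5, SE 0.12), Bag2 (log2 0.76, SE 0.19) and ENSMUSG00000079587 (log2 -0.96, SE 0.24). The genes named in advance had log2 values of -0.16 for Dnmt3a, -0.16 for Dnmt1, 0.14 for Fkbp5, -0.05 for Drd1, -0.2 for Drd2 and -0.32 for Esr1, none of which passed.

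Glucocorticoid-responsive genes were higher in stressed males as a list, with 16 of 19 positive (median log2 0.14; adjusted p = 0.000745, and adjusted p = 0.32 with an estimated correlation). Sgk1, a kinase induced by corticosteroids, had log2 0.31 and Tsc22d3 log2 0.43, and 0 members passed. Microglia markers were higher (median log2 0.12, 15 of 17 positive, adjusted p = 0.0151), as were oxidative phosphorylation subunits (median log2 0.12, 69 of 85 positive, adjusted p = 1.28e-06) and ribosomal protein genes (median log2 0.22, 76 of 79 positive, adjusted p = 3e-12). For these 3 lists the adjusted p was 0.32 with an estimated correlation. With the choroid plexus score as a covariate the medians were 0.08 for the glucocorticoid-responsive genes, 0.08 for microglia markers, 0.08 for oxidative phosphorylation subunits and 0.03 for ribosomal protein genes. The DNA methylation machinery was lower (median log2 -0.16, 15 of 18 negative, adjusted p = 0.00886, and adjusted p = 0.223 with an estimated correlation), with Tet3 at log2 -0.22 and Gadd45b at log2 -0.38, and its median was -0.07 with the choroid plexus score. Shared medium spiny neuron genes (median log2 -0.11, adjusted p = 0.0151), glutamate receptor and postsynaptic density genes (median log2 -0.08, adjusted p = 0.0362; Grin2b -0.46, Grin2a -0.36) and clustered protocadherins (median log2 -0.12, adjusted p = 0.00886) were lower, each with adjusted p = 0.32 with an estimated correlation. None of their members passed by either adjustment, and with the choroid plexus score the medians of these 3 lists were -0.14, -0.06 and -0.07.

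The choroid plexus list holds genes of the choroid plexus, which makes cerebrospinal fluid, and of the ependyma, which lines the ventricles. Its genes were lower in stressed males (median log2 -2.88, 13 of 14 negative, adjusted p = 1.6e-05, and adjusted p = 0.378 with an estimated correlation), 9 of them when adjusted over the list alone. The control males were uneven in these genes: Ttr, the choroid plexus transthyretin, was at 8.35, 958 and 2280 CPM in their 3 libraries and at 115, 34.2 and 140 in stressed males. Meningeal genes were lower too (median log2 -0.25, 10 of 13 negative, adjusted p = 0.0025, and adjusted p = 0.262 with an estimated correlation), with Igf2 (log2 -1.48) and Igfbp2 (log2 -1.59) passing adjusted over the list alone.

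With edgeR, Fos was the only gene called for stress in males, with 429 genes at an unadjusted p below 0.05 and 1206 (7.91%) with no overlap between the groups where chance gives 10%. DESeq2 called 4 genes and limma-voom 0. The Fos call was lost without control female library 2, control male library 2 or 3, or any of the 3 stressed male libraries (adjusted p 0.00218 to 0.323 over the 12 fits that leave out a library, log2 -1.9 to -1.54). It was also lost in a fit of only the 2 groups (log2 -1.71, adjusted p = 0.0776) and with a cortical (log2 -1.71, 0.0561) or choroid plexus (log2 -1.57, 0.117) score as a covariate, in a range of adjusted p over alternatives that begins at 7.98e-10. Of 29 lists 11 were called, and 6 without stressed male library 1.

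Averaged over the sexes, stress lowered Fos, to 7.11 ± 0.996 from 19.7 ± 4.16 CPM (n = 6 libraries each; log2 -1.47, SE 0.15, adjusted p = 0.00234), and Npas4, to 11.3 ± 1.5 from 22.9 ± 5.37 CPM (log2 -1, SE 0.12, adjusted p = 0.0156). Both were lower in 6 of 6 stressed libraries than in the controls of their sex. No other gene was called, with 489 at an unadjusted p below 0.05, and DESeq2 called 12 (2 higher and 10 lower). Fos passed in all 12 fits that leave out a library. Npas4 did not pass in 7 of them, without control female library 2, control male library 1 or 2, stressed female library 2 or 3, or stressed male library 2 or 3 (adjusted p up to 0.108), nor with the cortical marker score (0.143), where its log2 was -0.96. Under the other alternatives Npas4 passed, with an adjusted p from 1.08e-08 with DESeq2 to 0.0334 with the choroid plexus score, and 0.00293 with the replicate block. There were 3 genes called without control female library 3.

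Of the genes at an unadjusted p below 0.05 and at least 1.3-fold, 21 moved the same way in both sexes, where the list sizes alone give 2.46. Of them 7 were higher (0.61 expected) and 14 lower (1.85 expected), and 4 further genes moved in opposite ways (2.19 expected). That expectation takes the female and male lists as independent, although a single fit estimated the spread of each gene for both sexes. The excess is thus no test of a shared response. The 21 include Npas4, Fos, Arc, Egr1, Egr2, Nr4a1, Dusp1, Fosl2 and Sik1 among the immediate early genes, and Resp18 and Crh. Their number was 35 without stressed female library 1 and 32 without control female library 3. Across 14112 autosomal genes, which are not independent replicates, the female and male stress effects correlated at r = 0.135 (exact permutation p = 0.57) and rho = 0.216 (p = 0.5), with adjusted p of 0.69 and 0.78 over the 6 pairs of contrasts.

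The stress effect itself was compared between the sexes with an interaction test. No gene passed with edgeR, where 182 had an unadjusted p below 0.05. Smallest in p were Prkag2os1, an antisense RNA near the detection limit (log2 -4.09, adjusted p = 0.734), Bglap3 (log2 2.55) and Sulf1 (log2 0.87). The immediate early genes did not differ by this test (median log2 difference, female minus male, -0.15, adjusted p = 0.759). At the preset correlation 6 lists did, among them cortical markers (median log2 difference -0.66, adjusted p = 4.51e-05), glucocorticoid-responsive genes (-0.23, adjusted p = 1.33e-05) and endothelial markers (-0.22, adjusted p = 0.0196). So did oligodendrocyte precursor markers (0.16, adjusted p = 0.0376), imprinted genes (0.13, adjusted p = 0.0242) and choroid plexus genes (3.4, adjusted p = 4e-06). None passed with an estimated correlation (adjusted p of 0.331 to 0.635), and 3 lists were called without control male library 2 or stressed female library 2 or 3.

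**Figure D2:**
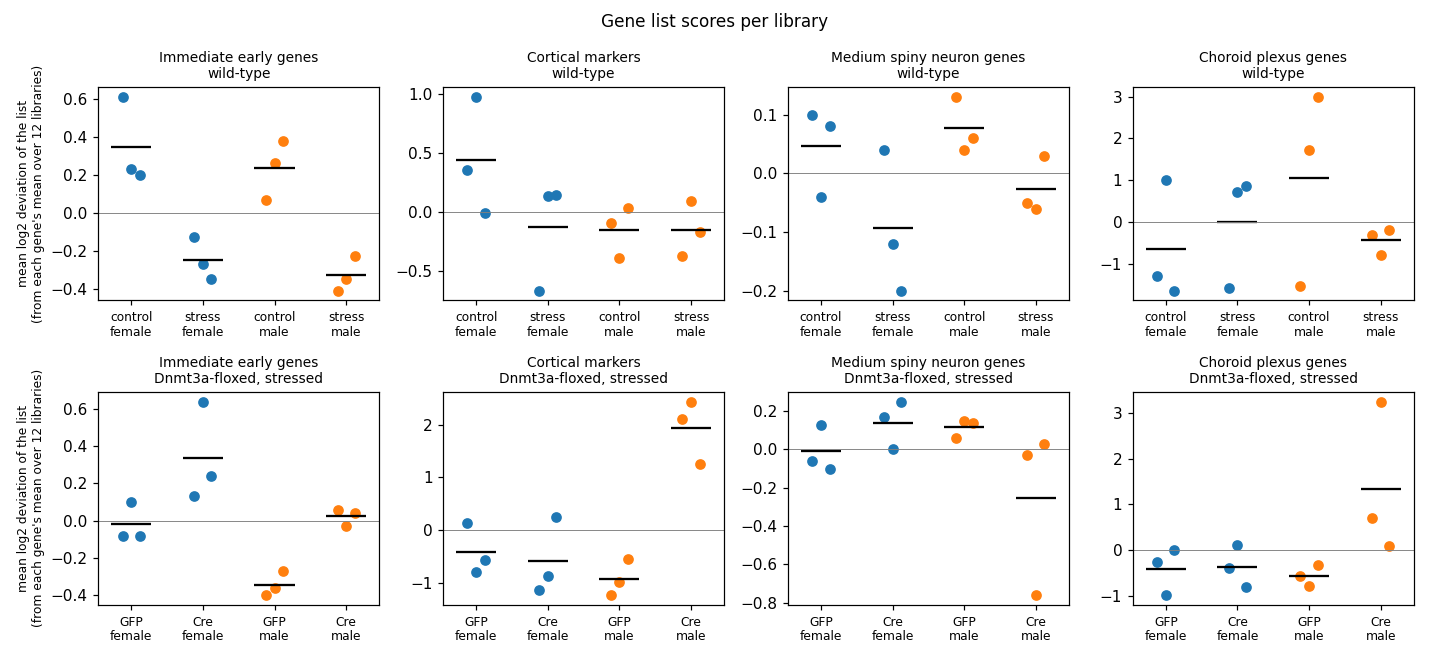
Mean log2 deviation of 4 gene lists from their mean over the 12 libraries of an experiment, on the vertical axis, by group. Each point is a library and the bar is the mean of 3; the immediate early gene score was 0.35 ± 0.23 in control and -0.25 ± 0.11 in stressed females, and 0.24 ± 0.16 in control and -0.33 ± 0.09 in stressed males.

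The floxed experiment asks what loss of Dnmt3a, a DNA methyltransferase that writes new methylation, does to expression in stressed females and males. Dnmt3a itself was at 155, 150 and 140 CPM in the Cre female libraries and 162, 169 and 155 in the GFP female libraries, and at 143, 137 and 138 in the Cre male and 182, 164 and 171 in the GFP male libraries. In males it fell 1.24-fold (140 ± 2.99 against 172 ± 8.63 CPM, n = 3; log2 -0.3, SE 0.06, adjusted p = 0.0149, lower in 3 of 3 libraries). In females it did not pass (148 ± 7.89 against 162 ± 7.19 CPM; log2 -0.12, SE 0.06, adjusted p = 0.829). The effects did not differ between the sexes by the interaction test (log2 difference 0.18, SE 0.08, adjusted p = 0.269). A count over the whole gene includes reads from outside the deleted part, from cells without virus and, where reads were not counted by strand, from an overlapping gene, so these values do not measure the share of deleted copies. The male call was lost without GFP male library 1 or 3 (adjusted p up to 0.0583) and with a cortical (log2 -0.14, adjusted p = 1) or choroid plexus (log2 -0.29, adjusted p = 0.112) score as a covariate, in a range that begins at 1.62e-05.

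In Cre females, immediate early genes were higher as a list than in GFP females, with 22 of 23 positive (median log2 0.37; adjusted p = 4.62e-09, and adjusted p = 0.308 with an estimated correlation). Of them 6 passed adjusted over the list alone, all higher, and 0 over all genes; the transcription factor genes Egr4 (log2 1.17, SE 0.24), Junb (log2 0.94, SE 0.2) and Jun (log2 0.41, SE 0.1) had the smallest p. Fos was at 11.6, 31 and 8.43 CPM in Cre and 8.58, 13.5 and 9.75 in GFP females, and its log2 of 0.67 was -0.09 without Cre female library 2. Of single genes, C1qtnf4, a secreted C1q and TNF related protein, stood at 48.7 ± 8.63 CPM in Cre against 15.9 ± 5.93 in GFP females (n = 3; log2 1.62, SE 0.29) and Ier5l at 8.3 ± 1.76 against 2.54 ± 1.11 (log2 1.71, SE 0.33). Neither passed, nor did the other 8 genes of smallest p, all higher with Cre: H2afx (0.5), Zfp865 (0.57), Akt1s1 (0.47), Mex3a (0.54), Rprml (0.6), Icam5 (0.52), Rex1bd (0.44) and ENSMUSG00000042878 (0.5), with log2 values in brackets and an adjusted p of 0.448 for each. H2afx, Zfp865, Akt1s1, Mex3a and Icam5 overlap other genes.

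Other lists in Cre females had smaller shifts, and all lost their call with an estimated correlation (adjusted p of 0.308 for glucocorticoid-responsive genes, 0.666 for interneuron markers, 0.718 for endothelial markers and 0.835 for the rest). Shared medium spiny neuron genes were higher in 20 of 20 (median log2 0.15, adjusted p = 0.0181), as were glucocorticoid-responsive genes in 18 of 21 (median log2 0.13, adjusted p = 0.00539; Ddit4 0.32, Per1 0.22) and ribosomal protein genes in 65 of 83 (median log2 0.03, adjusted p = 0.0181). Interferon and antigen presentation genes were lower in 26 of 27 (median log2 -0.21, adjusted p = 0.0122; Oas2 -0.73, Ifit2 -0.26). Their scores spread far wider than this shift, at -1.06, -0.17 and 0.61 in Cre and -0.28, 0.76 and -0.15 in GFP females. Striatal interneuron markers (median log2 -0.25, adjusted p = 0.00778), endothelial markers (median log2 -0.1, adjusted p = 0.00539) and meningeal genes (median log2 -0.16, adjusted p = 0.0391) were lower, with log2 -1.51 for Pvalb, the parvalbumin of fast-spiking interneurons. No member of these lists passed by either adjustment. Of the genes named in advance, Drd1 (log2 0.15), Drd2 (0.2), Esr1 (-0.81), Fkbp5 (0.12), Dnmt1 (-0.03) and Dnmt3b (0.25) did not pass.

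For Cre in females edgeR called 0 genes, with 1049 at an unadjusted p below 0.05 and 2031 (11.5%) with no overlap between the groups where chance gives 10%. DESeq2 called 34 genes, 33 of them higher, and limma-voom 0. Of 29 lists 8 were called, and 5 without Cre female library 1 or GFP female library 3.

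In Cre males, genes that mark cortical excitatory neurons were far higher than in GFP males. Slc17a7 was at 428, 408 and 168 CPM in the Cre libraries and 1.29, 2.76 and 15.3 in the GFP libraries (log2 5.62, SE 1.31, adjusted p = 0.0431). Tbr1, a transcription factor of deep cortical layers, was at 36.8 ± 14.8 against 1.58 ± 0.624 CPM (n = 3; log2 4.51, SE 0.82, adjusted p = 0.0186). Cck, a neuropeptide of cortical neurons and interneurons, was at 33.7 ± 11.7 against 2.09 ± 0.689 (log2 3.99, SE 0.55, adjusted p = 0.00813). Of the 16 cortical and other excitatory neuron markers 15 were positive (median log2 3.01; adjusted p = 5.19e-09, and adjusted p = 0.52 with an estimated correlation). Of them 11 were called higher over all genes, with Neurod1 (log2 5.98) and Slc30a3 (log2 5.59), and 13 were higher and 1 lower adjusted over the list alone. The list's score was 2.1, 2.44 and 1.26 in the Cre male libraries and at most 0.25 in the other 9.

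Among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, the others with the largest rise in Cre males were Nrn1, an activity-regulated growth factor (log2 4.36, adjusted p = 0.0173), the matricellular Ccn3 (4.13, 0.00968), the brain protease gene Prss12 (3.95, 0.0154) and the nuclear receptor Nr4a2 (3.47, 0.0108). They also include the neurexin ligand Nxph3 (3.2, 0.00623), the Nogo receptor Rtn4r (2.87, 0.00324), the synaptic C1ql3 (2.82, 0.00623), the Wnt inhibitor Frzb (2.64, 0.00359) and the microRNA gene Gm23935 (3.51, 0.0314). All were higher in 3 of 3 libraries. The largest falls among such genes were near 2-fold. Calcr, the calcitonin receptor, was at 13.2 ± 3.01 against 26.5 ± 2.92 CPM (log2 -1.01, SE 0.23, adjusted p = 0.0368) and Drd3, a dopamine receptor, at 6.98 ± 1.62 against 11.5 ± 1.16 (log2 -0.73, SE 0.17, adjusted p = 0.033). The other 10 were Mcmdc2 (log2 -1.06), Gm3828 (-1.02), Rasgrp4 (-1), Col28a1 (-0.84), ENSMUSG00000091089 (-0.83), Rgsl1 (-0.82), Bend7 (-0.8), C230014O12Rik (-0.79), Myh6 (-0.77) and Adamts6 (-0.73). Each of the 12 was lower in 3 of 3 libraries, with an adjusted p of 0.0148 to 0.0406. Cck, Nxph3, Rtn4r, C1ql3 and Frzb passed in all 12 fits that leave out a library. Slc17a7, Tbr1 and Nrn1 did not pass without Cre male library 1 or 2 or any of the 3 GFP male libraries, nor Slc17a7 without GFP female library 2 (adjusted p up to 0.142 for Slc17a7, 0.0776 for Tbr1 and 0.082 for Nrn1). Ccn3 and Nr4a2 did not pass without GFP male library 2 (up to 0.0533 and 0.0584), nor Prss12 and Gm23935 without Cre male library 2 or any of the 3 GFP male libraries (up to 0.0755 and 0.119). Each of the 12 lower genes was lost in at least 3 fits, with a highest adjusted p of 0.0533 for Myh6 to 0.135 for Calcr.

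Receptor and synaptic genes changed in both directions in Cre males, whose libraries were high in cortical markers. With the cortical score as a covariate none of them was called, so RNA from neighbouring cortex and an effect of Cre cannot be told apart. Of 32 hormone, neuropeptide and monoamine receptors 5 were called higher, Crhbp, which binds corticotropin-releasing hormone (log2 1.56), the oxytocin receptor Oxtr (1.64), Esr1 (1.51), the neurotensin receptor Ntsr1 (1.88) and Esrra (0.31), and 1 lower, Drd3. Adjusted over the list alone, 6 were higher and 2 lower, and the list did not move as a whole (adjusted p = 0.436). Esr1 rose to 4.59 ± 2.17 from 1.63 ± 0.153 CPM (adjusted p = 0.0285) and lost its call without Cre male library 1 or 2 or any of the 3 GFP male libraries (adjusted p up to 0.111). Synaptic vesicle release genes were higher as a list (median log2 0.15, adjusted p = 0.0125, and adjusted p = 0.595 with an estimated correlation). Of them 7 were called higher, among them Stx1a (1.01), Cplx3 (3.3) and Syn1 (0.51), and 1 lower, Unc13c (-0.55). Adjusted over the list alone, 13 were higher and 4 lower, and the median was 0.03 with the cortical and 0.07 with the choroid plexus score as a covariate. With a GC correction it was 0.07. Glutamate receptor and postsynaptic density genes did not move as a list (adjusted p = 0.87). Grm2 (1.56), Dlgap1 (0.75) and Grik3 (0.32) were called higher and Grm7 (-0.29) and Grik2 (-0.46) lower, with 4 higher and 4 lower adjusted over the list alone. Of GABA signalling genes (adjusted p = 0.101) Gabbr2 (0.69) was called, and 1 was higher and 1 lower adjusted over the list alone. Drd1 (216 ± 68 against 293 ± 13.1 CPM, log2 -0.44, adjusted p = 0.21), Drd2 (log2 -0.38, 0.326), Fos (0.31, 0.695), Fkbp5 (-0.22, 0.26), Dnmt1 (0.04, 0.741) and Dnmt3b (-0.13, 0.737) did not pass.

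Of the striatal neuron lists, 2 moved in Cre males at the preset correlation. Shared medium spiny neuron genes were lower in 20 of 20 (median log2 -0.32, adjusted p = 4.17e-05, and adjusted p = 0.595 with an estimated correlation), with 0 called and Ptpn5 at log2 -0.41 and Gnal at log2 -0.43. Their score was -0.03, -0.76 and 0.03 in the 3 Cre male libraries against 0.12 ± 0.05 in GFP males, so library 2 carries most of the shift, and their median was 0 with the cortical and 0.13 with the choroid plexus score as a covariate. D1 markers (median log2 -0.38, adjusted p = 0.0536) and D2 markers (median log2 -0.33, adjusted p = 0.0867) did not pass as lists. Of the D1 markers Isl1 (log2 -0.65) was called lower and Eya1 (log2 0.69) higher, with 2 lower and 1 higher adjusted over the list alone. Striatal interneuron markers were higher (median log2 0.36, 8 of 13 positive, adjusted p = 0.0123, and adjusted p = 0.59 with an estimated correlation), with the neuropeptide genes Sst (0.54), Vip (3.07), Npy (0.44) and Cck called and 6 higher adjusted over the list alone. Their median was 0.06 with the cortical and 0.13 with the choroid plexus score. Immediate early genes were higher (median log2 0.26, 15 of 23 positive, adjusted p = 0.0107, and adjusted p = 0.595 with an estimated correlation), with Jun (0.98), Nr4a2, Dusp6 (0.44) and Junb (0.8) called and 5 adjusted over the list alone, and their median was 0.37 with the cortical and 0.15 with the choroid plexus score.

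Several lists of glial and border tissue genes were also higher in Cre males, with libraries that stand apart. Choroid plexus genes had a median log2 of 2.78 (12 of 14 positive, adjusted p = 0.00301, and adjusted p = 0.595 with an estimated correlation), with 0 called and 7 higher adjusted over the list alone. Ttr was at 125, 1850 and 23.8 CPM in the Cre libraries against 0.952, 1.48 and 15.3 in the GFP libraries. Oligodendrocyte precursor markers were higher in 9 of 10 (median log2 0.22, adjusted p = 0.00408, and adjusted p = 0.52 with an estimated correlation), with Olig1 (0.65) and C1ql1 (0.72) called and 4 adjusted over the list alone. Oligodendrocyte and myelin genes (median log2 0.23, 20 of 20 positive, adjusted p = 0.00596), astrocyte markers (0.13, 15 of 17, adjusted p = 0.021), reactive glia genes (0.46, 17 of 20, adjusted p = 0.0223) and meningeal genes (0.28, 11 of 13, adjusted p = 0.046) were higher too. These 4 lists had 0 members called and an adjusted p of 0.595 with an estimated correlation. The scores of the 3 Cre male libraries were -0.14, 0.51 and 0.07 for oligodendrocyte genes (GFP males -0.13 to 0.02), 0.69, -0.46 and 0.38 for reactive glia genes (-0.44 to 0.02) and -0.07, 0.64 and -0.06 for meningeal genes (-0.36 to -0.06). With the cortical and with the choroid plexus score as a covariate the medians were -0.19 and -0.08 for oligodendrocyte genes, 0.07 and 0.03 for astrocyte markers, 0.39 and -0.01 for meningeal genes, 0.2 and 0.14 for oligodendrocyte precursor markers, 0.84 and 1.06 for reactive glia genes, 0.24 and 0.57 for microglia markers, and -0.23 and 0.05 for choroid plexus genes. Microglia markers were positive in 17 of 17 (median log2 0.2, adjusted p = 0.046, and adjusted p = 0.664 with an estimated correlation), with scores of 0.21, -0.24 and 0.33 against -0.21 to 0 in GFP males. Glucocorticoid-responsive genes were higher (median log2 0.2, 17 of 21 positive, adjusted p = 0.0125, and adjusted p = 0.52 with an estimated correlation), with Zbtb16 (0.77) called, also adjusted over the list alone. Their median was 0.15 with the cortical and 0.08 with the choroid plexus score. With a GC correction the medians were 0.07 for oligodendrocyte precursor markers, 0.07 for astrocyte markers, 0.13 for meningeal genes and 0.11 for glucocorticoid-responsive genes. They were 2.76 for choroid plexus genes, 0.18 for oligodendrocyte genes, 0.42 for reactive glia genes and 0.18 for microglia markers.

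Of the 3 lists of known targets of DNA methylation, 1 was lower in Cre males. Its genes, the clustered protocadherins, were negative in 23 of 24 (median log2 -0.26, adjusted p = 1.85e-06, and adjusted p = 0.59 with an estimated correlation), with Pcdhb15 (-0.44) called and 12 lower and 1 higher adjusted over the list alone. Their median was 0.03 with the cortical and -0.08 with the choroid plexus score as a covariate. Ribosomal protein genes (median log2 -0.11, 67 of 83 negative, adjusted p = 0.000312, and adjusted p = 0.595 with an estimated correlation) were lower. So were blood genes (median log2 -0.66, 5 of 5 negative, adjusted p = 0.00408, and adjusted p = 0.59 with an estimated correlation; 4 lower adjusted over the list alone). With the cortical and with the choroid plexus score the medians were -0.09 and 0.02 for ribosomal protein genes and 0.36 and -0.37 for blood genes. Oxidative phosphorylation subunits were higher (median log2 0.04, which was -0.01 with a GC correction; adjusted p = 0.0364, and adjusted p = 0.598 with an estimated correlation), with Uqcrq (0.59) called. Imprinted genes (median log2 0.01 although the test's direction was down, adjusted p = 0.238; Peg10 at -0.72 called, and 2 higher and 4 lower adjusted over the list alone) and germline genes (adjusted p = 0.253; none called) did not move as lists. Nor did the DNA methylation machinery (adjusted p = 0.169), in which Dnmt3a and Tet2 (-0.27), an enzyme that oxidises methylcytosine, were called lower, by both adjustments. Heat shock genes (adjusted p = 0.0536) had 2 called, the near-identical Hspa1a (2.37) and Hspa1b (3.15), and 3 higher adjusted over the list alone. Interferon and antigen presentation genes (adjusted p = 0.0956), endothelial markers (adjusted p = 0.133) and septal, pallidal and hypothalamic markers (adjusted p = 0.298) had 0 called.

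In total edgeR called 872 genes for Cre in males, 647 higher (74.2%) and 225 lower, with 4369 at an unadjusted p below 0.05 and 5174 (29.4%) with no overlap between the groups where chance gives 10%. DESeq2 called 1135 higher and 676 lower, and with a correction for GC content 371 were higher and 550 lower, with 558 of the 872 calls kept. With the cortical marker score as a covariate 0 genes were called. Of the 17597 genes tested, 443 then had an unadjusted p below 0.05 where chance would give 880. With the choroid plexus score 37 genes were called. The count was 318 without Cre male library 1, 341 without Cre male library 2, and 246, 93 and 165 without GFP male library 1, 2 and 3, and 17 of 29 lists were called.

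Averaged over the sexes, Cre raised Rasl10a, a Ras-like GTPase (7.26 ± 3.18 against 2.52 ± 0.573 CPM, n = 6 libraries each; log2 1.45, SE 0.14, adjusted p = 0.00358) and Rprml (19.6 ± 1.71 against 11.4 ± 1.8 CPM; log2 0.79, SE 0.08, adjusted p = 0.00358). It also raised the transcription factor gene Jun (27.8 ± 3.14 against 17.2 ± 2.96 CPM; log2 0.7, SE 0.07, adjusted p = 0.0037), Zfp703 (log2 0.74, adjusted p = 0.00358) and Csf2ra (log2 0.44, adjusted p = 0.00521). These 5 passed in all 12 fits that leave out a library. The lower genes of smallest p were Amy1 (log2 -0.21, adjusted p = 0.0232), the adhesion protein Cntnap2 (log2 -0.21, adjusted p = 0.0237) and Dnmt3a (144 ± 7.25 against 167 ± 9.14 CPM; log2 -0.21, adjusted p = 0.026). Next were the synaptic priming protein Unc13c (log2 -0.31, adjusted p = 0.0282) and Vmn1r-ps128 (log2 -0.53, adjusted p = 0.0315). These 5 each lost their call in 7 to 10 of those fits (adjusted p up to 0.0758 for Dnmt3a and 0.089 for Vmn1r-ps128). The Dnmt3a call was also lost with the choroid plexus score (log2 -0.21, adjusted p = 0.0578) and with the GC correction and replicate block (log2 -0.24, adjusted p = 0.0547). It was lost with the cortical score too (log2 -0.14), in a range of adjusted p over alternatives that begins at 2.57e-05.

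In all, 249 genes were called for the averaged Cre effect, 228 higher (91.6%) and 21 lower, with 2506 at an unadjusted p below 0.05. DESeq2 called 513 higher and 139 lower, a GC correction left 73 higher and 23 lower, with 76 of the 249 calls kept, and 0 were called with the cortical marker score as a covariate. The count was 143, 106 and 47 without Cre female library 1, 2 and 3, 114 without Cre male library 1, 35, 44 and 401 without GFP female library 1, 2 and 3, and 129, 17 and 31 without GFP male library 1, 2 and 3. Among genes at an unadjusted p below 0.05 and at least 1.3-fold, 84 were higher in both sexes (19 expected from the list sizes alone). Another 4 were lower in both (5.2 expected) and 58 moved in opposite ways (20.6 expected). Here too the expectation takes the lists of the sexes as independent, which a shared fit does not ensure, so the excess is no test. The 84 include Egr4, Junb, Jun, Jund, Gadd45b, C1qtnf4, Ier5l, Rprml and Vgf. Of the 872 genes called in males 452 (51.8%) had the same sign in females. Across 16138 autosomal genes the Cre effects of the sexes correlated at r = -0.136 (exact permutation p = 0.53) and rho = -0.16 (p = 0.54), with adjusted p of 0.69 and 0.78.

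The interaction test asks whether Cre changed expression differently in females and males. It called Ccn2, a matricellular growth factor and a marker of deep cortical layers (log2 difference, female minus male, -3.02, SE 0.36, adjusted p = 0.0246). Ccn2 was at 11.8, 8.4 and 7.71 CPM in Cre and 2.11, 1.48 and 1.86 in GFP males against 1.54, 1.75 and 1.5 in Cre and 3.6, 1.95 and 2.03 in GFP females. It also called Adcyap1, the neuropeptide PACAP, at 4.51, 3.22 and 2.61 CPM in Cre and at most 0.255 in GFP males, and at most 0.4 in all 6 female libraries (log2 difference -4.86, SE 0.58, adjusted p = 0.0246). Each lost its call in 7 of the 12 fits that leave out a library (adjusted p 0.00233 to 0.146). These were the fits without Cre female library 2, Cre male library 1, GFP female library 3 or any of the 3 GFP male libraries, and for Ccn2 also Cre female library 1, for Adcyap1 GFP female library 1. Of the lists, 15 differed at the preset correlation and 0 with an estimated correlation, and the cortical markers (median log2 difference -3.77) and interneuron markers (-0.62) also differed with fry (adjusted p = 0.0227 for each).

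These were the only 2 genes called by edgeR for this interaction, with 3082 at an unadjusted p below 0.05. DESeq2 called 606, limma-voom 0, edgeR without a filter 43, with a replicate block 1, and with the cortical marker or the choroid plexus score as a covariate 0. The count was 500 without Cre male library 3, 144 without GFP female library 2, and 20 without Cre female library 3. It was 1 without Cre female library 1 or GFP female library 1, and 0 without Cre female library 2, Cre male library 1, GFP female library 3 or any of the 3 GFP male libraries.

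The remaining comparisons ask whether Cre moved expression against the stress effect or towards the other sex. The Cre effect of floxed females correlated with the stress effect of wild-type females at r = -0.135 (exact permutation p = 0.24) and rho = -0.157 (p = 0.26) across 13874 autosomal genes. That of males correlated with the male stress effect at r = -0.123 (p = 0.49) and rho = -0.041 (p = 0.78). The female Cre effect correlated with the male minus female difference of stressed wild-type mice at r = 0.045 (exact permutation p = 0.69) and rho = 0.052 (p = 0.78). The female stress effect correlated with that difference in GFP mice at r = -0.052 (p = 0.63) and rho = -0.046 (p = 0.69). The adjusted p was 0.69 for r and 0.78 for rho in each of the 6 pairs tested, and genes are not independent replicates. Over the 12 fits that leave out a library, r of the female Cre and stress effects ranged from -0.232 (without stressed female library 1, permutation p = 0.04, not adjusted over the fits) to 0.008 (without stressed female library 3, p = 0.95).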

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

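The tests with a cortical score, a GC or gene length correction or thinned libraries were chosen after the data were seen, those of cortical RNA and GC content in the Cre results and of the male cortical score also after the results they examine, and the splits before. What stands out here is a difference between the sexes in the effect of Cre or of stress, by the interaction test, with values given as female minus male on the log2 scale. For Cre, Ccn2 (-3.02) and Adcyap1 (-4.86) differed (adjusted p = 0.0246 for each). They rose with Cre in 3 of 3 male libraries.

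For Cre, 15 lists also differed. Lower in the female effect were cortical markers (median -3.77), choroid plexus genes (-3.14), interferon and antigen presentation genes (-0.68), striatal interneuron markers (-0.62), meningeal genes (-0.6), reactive glia genes (-0.44), oligodendrocyte genes (-0.33), oligodendrocyte precursor markers (-0.33), microglia markers (-0.27), synaptic vesicle release genes (-0.21) and astrocyte markers (-0.15). Higher were D2 markers (0.56), shared medium spiny neuron genes (0.48), clustered protocadherins (0.31) and ribosomal protein genes (0.14). For stress, 6 lists differed: choroid plexus genes (3.4), oligodendrocyte precursor markers (0.16), imprinted genes (0.13), endothelial markers (-0.22), glucocorticoid-responsive genes (-0.23) and cortical markers (-0.66). None of these 21 list calls held with an estimated correlation. With the cortical and with the choroid plexus score as a covariate the Cre medians were 0.11 and 0.05 for D2 markers, 0.18 and 0.07 for shared medium spiny neuron genes, -0.01 and 0.11 for protocadherins, 0.12 and 0.01 for ribosomal protein genes, -0.05 and -2.43 for cortical markers, 0.31 and 0.16 for choroid plexus genes, -0.45 and -1.38 for interferon genes, -0.22 and -0.38 for interneuron markers, -0.52 and -0.21 for meningeal genes, -0.91 and -0.99 for reactive glia genes, 0.09 and -0.04 for oligodendrocyte genes, -0.31 and -0.24 for oligodendrocyte precursor markers, -0.32 and -0.73 for microglia markers, -0.09 and -0.13 for synaptic vesicle genes, and -0.11 and -0.02 for astrocyte markers. The stress medians were 4.98 and -0.01 for choroid plexus genes, 0.24 and 0.14 for oligodendrocyte precursor markers, 0.19 and 0.05 for imprinted genes, -0.25 and -0.12 for endothelial markers, -0.3 and -0.18 for glucocorticoid-responsive genes, and 0.07 and -1.08 for cortical markers.

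Other splits of the same libraries were fitted to ask whether chance can be excluded. It cannot for the interaction of Cre with sex (2 genes, where 4 of 30 splits gave as many and the highest other gave 69; 15 lists, 4 of 30 splits, highest other 15), nor for the lists of that of stress with sex (6 lists, 8 of 30 splits, highest other 10). With 0 genes called for the latter, all 30 of 30 splits are as large (highest other 1712), so their number says nothing. For the averaged stress effect (2 genes, 2 of 30 splits, highest other 4) and for sex in wild-type mice (6 genes, 3 of 30 splits, highest other 3251) the count alone does not exclude chance. For sex, Xist, Kdm5d, Uty, Ddx3y and Eif2s3y nevertheless parted all 6 female from all 6 male libraries and passed in all 12 fits that leave out a library, so for these 5 genes chance is excluded. For the averaged Cre effect (249 genes, 1 of 30 splits, highest other 36) and for sex in floxed mice (12 genes, 1 of 30 splits, highest other 2) no other drawn split was as large. This argues against chance for these counts, but only some of the possible splits were drawn and the shares were not adjusted over the contrasts. The averaged Cre count also rests on single libraries, with 17 genes without GFP male library 2. The wild-type splits with 3251, 1809 and 1712 genes, and that with 4, put all 4 libraries of replicate 1 on the same side, which points to a structure of the samples, although another such split for sex called 0. Apart from the real ones, they are the only splits as large for the averaged stress effect and for sex. With a replicate block the real counts were 7 for sex, 0 for the interaction and 4 for the averaged stress effect.

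Within a sex the 10 splits are too few for a share under 0.05. The real count and the highest other were 0 and 0 genes (10 of 10 splits as large) and 8 and 8 lists (2 of 10) for stress in females, 1 and 0 genes (1 of 10) and 11 and 7 lists (1 of 10) for stress in males, 0 and 0 genes (10 of 10) and 8 and 13 lists (7 of 10) for Cre in females, and 872 and 0 genes (1 of 10) and 17 and 13 lists (1 of 10) for Cre in males.

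The first pattern weighed is the rise of cortical markers in Cre males, for which RNA from neighbouring cortex in the punches is a candidate explanation beside an effect of Cre. Deeper sequencing is argued against, since 738 of the 872 genes (84.6%) were still called with all floxed libraries thinned to the lowest total. If cortical RNA were the source, genes called higher should rise with the cortical score within the wild-type groups, and 51.6% did (306 of 593, permutation p = 0.52, with 50.5% of all tested genes), as did 80.6% of those at 4-fold or more (29 of 36, p = 0.0486, and 0.146 adjusted over the 3 sets tried) and 49.7% below 4-fold (277 of 557, p = 0.528). The 4-fold division was made after the result for all genes was seen. Within the wild-type groups the cortical score also varied little (SD 0.48 in females and 0.23 in males), against a median log2 rise of 3.01 of these markers in Cre males. The test could thus miss a cortical source, and none of the 3 values decides. With the cortical score as a covariate the median log2 change of the 872 genes went from 0.52 to 0.31. The median of the SEs of the single genes went from 0.11 to 0.26, so cortical RNA and an effect of Cre cannot be told apart.

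The second pattern is the excess of higher genes in the averaged Cre effect, whose median GC content was 59.1% against 50% for all tested genes. After a GC correction 71 of the 228 were still called higher, with an adjusted p over all genes of at most 0.0495. This argues against a GC bias as the whole cause of these 71 calls. The median log2 change of the 228 went from 0.46 to 0.34 (median SE of a single gene 0.08 and 0.07). The 228 were picked for high values in the same data, so a median that stays positive after a correction decides nothing. For the 157 whose call ended, the median went from 0.4 to 0.25, with a median SE of a single gene of 0.07 before and after. The correction itself picked these genes, so this decides nothing and a GC bias stays open for them. After a gene length correction 144 were still called higher (median log2 0.41 over the 228), which argues against length as the whole cause of these 144 calls. The Cre male libraries, with their higher cortical score, enter this average, so RNA from neighbouring cortex stays open here too. An effect of Dnmt3a loss or of the virus also stays open and was not tested apart.

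The third pattern is the lower immediate early genes after stress in both sexes. A lower share of cortical tissue is argued against in females, since with the cortical score as a covariate their median log2 change was -0.61 (22 of 23 lower), and so is a GC bias, with -0.58 in females and -0.57 in males after the correction (23 of 23 lower in each). In males the covariate (-0.58) had nothing to remove and is no test, but the cortical score of stressed minus control libraries was 0 (SE 0.19), which argues against a lower cortical share as the cause of a fall of -0.57. In both sexes the lowest control score (0.2 in females, 0.07 in males) lay above the highest stressed score (-0.13 and -0.23). The time and handling between the last stressor and tissue collection, and a biological effect of stress, stay open and were not tested.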

How the results depend on the processing

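The covariates, the GC and gene length corrections and the thinning of libraries were chosen after seeing the data, and the other alternatives before. The direction and the side of the threshold held under all alternatives counted for 45 of 126 pairs of a named gene and a contrast, and 18 pairs had a reversal, 4 of them among the 57 past the threshold. Dnmt3a with Cre in females and in males is not among these 126 pairs, and its male call was lost with either score as a covariate. Of the fits that leave out a library, only those with a gene's lowest and highest fold change were counted. The 45 is thus an upper limit. With RLE factors every count stayed within 1.5 times its main value. Where a value below differs and no reason is given, the cause was not tested. Simulated genes changed 1.5-fold were recovered in 11.9% of cases at the depth and spread of the male stress comparison and in 67.2% at those of the male Cre comparison. The simulated genes were independent of each other, so these shares need not hold in the real data.

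Without a filter, 5 genes were called for stress in females, 3 in males, 12 averaged, 14 for sex in wild-type mice and 43 for the interaction of Cre with sex. DESeq2 called 2, 4 and 12 for stress (females, males, averaged), 13 and 89 for sex (wild-type, floxed), 34, 1811 and 652 for Cre (females, males, averaged) and 606 for its interaction with sex. Limma-voom called 0 for stress in males (429 at an unadjusted p below 0.05 with edgeR) and 0 for the interaction of Cre with sex (3082). A fit of only the 2 groups, with fewer libraries for the spread, called 0 for stress in males and 551 for Cre in males. With a replicate block the counts were 4 for averaged stress, 515 for Cre in males, 87 for averaged Cre and 1 for the interaction of Cre with sex. At an unadjusted p below 0.05 and 1.3-fold, a looser rule, they were 205, 346 and 251 for stress, 179 for its interaction, 424, 1860 and 627 for Cre, 1901 for its interaction, and 377 and 396 for sex. At an unadjusted p under 0.01, 8 genes were shared by the stress responses of the sexes. With an estimated correlation 1 list moved with stress in females and 1 in males, the immediate early genes, and 0 for the interaction of stress, 0 for Cre in females, 0 in males and 0 for its interaction. With fry these list counts were 1, 1, 0, 0, 4 and 2.

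With the cortical marker score as a covariate the edgeR counts were 0 for stress in males, 1 for averaged stress, 0 for Cre in males, averaged Cre and its interaction with sex, and 7 for sex in floxed mice, with 1 list for Cre in males and 4 for its interaction. Dnmt3a in Cre males was then at log2 -0.14, and reversed were, in Cre males, Slc17a7 (-0.74), Prss12 (-0.44), Tbr1 (-0.18), Drd2 (0), Adamts6 (0.01) and Dnmt3b (0.31). The score is made of markers such as Slc17a7 and Tbr1, so it removes their change by construction, and it raised the median SE of the male Cre calls from 0.11 to 0.26. With the choroid plexus score the counts were 0 for stress in males, 37 for Cre in males and 0 for its interaction, with 6 lists for stress in males, 14 for Cre in females and 9 for Cre in males. Dnmt3a in Cre males was at log2 -0.29, and reversed were Dnmt1 (-0.01) and Drd1 (0.02) in stressed females, Utp14a between floxed sexes (-0.04), and in Cre males Dnmt1 (-0.03), Fos (-0.01), Fkbp5 (0.08), Drd1 (0.09) and Drd2 (0.18).

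With the GC content correction the counts were 1 for stress in females, 8 averaged, 14 for sex in wild-type mice and 96 for averaged Cre, and Dnmt1 in Cre males was at -0.04. With the GC content correction and the replicate block they were 2, 2 and 12 for stress, 31 for sex in wild-type mice, 426 for Cre in males, 24 averaged and 1 for its interaction, and Dnmt1 in Cre males was at -0.04.

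Leaving out each library in turn gave 0 to 1 genes for stress in females, 0 to 1 in males, 1 to 3 averaged and 0 to 0 for its interaction, 0 to 0 for Cre in females, 93 to 1303 in males, 17 to 401 averaged and 0 to 500 for its interaction, and 5 to 6 and 9 to 92 for sex in wild-type and floxed mice. The list counts were 5 to 10 and 6 to 13 for stress, 3 to 8 for its interaction, 5 to 10 and 14 to 18 for Cre and 12 to 17 for its interaction, and 16 to 35 genes were shared by the stress responses. The libraries behind the changed counts are named with the counts in the report. Dnmt3a in Cre males ranged from -0.34 to -0.27 and in Cre females from -0.16 to -0.08. The correlation across genes, which are not independent replicates, ran from -0.002 (without control female library 2) to 0.209 for stress in the sexes and from -0.192 to 0.031 (without Cre female library 1) for Cre in the sexes. For the female Cre effect it ran from -0.232 to 0.008 (without stressed female library 3) against stress, and from -0.078 (without stressed female library 3) to 0.154 against the male minus female difference, also negative without stressed male library 3 (-0.002) or Cre female library 3 (-0.026). For the female stress effect against that difference in GFP mice it ran from -0.122 to 0.043 (without control female library 3), and for Cre against stress in males from -0.158 to -0.036. Named genes that reversed, none of which passes, were in stressed females Dnmt1 (-0.1 to 0.11), Fkbp5 (-0.1 to 0.01), Drd1 (-0.14 to 0.15) and Drd2 (-0.41 to 0), in stressed males Drd1 (-0.13 to 0.02), in Cre females Dnmt1 (-0.11 to 0.03) and Fos (-0.09 to 1), and between floxed sexes Utp14a (-0.04 to 0.05).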

Other observations

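The microRNA gene Gm23935 was high with Cre in both sexes. It was at 7.26, 10.7 and 5.18 CPM in Cre females against 0.429, 0.679 and 2.51 in GFP females (log2 2.67, SE 0.7, adjusted p = 0.582), and at 2.5, 6.65 and 11 CPM in Cre males against 0.918, 0.303 and 0.535 in GFP males. Averaged over the sexes it was called (log2 3.09, SE 0.51, adjusted p = 0.0249), higher in 6 of 6 Cre libraries than in the GFP libraries of its sex. It was singled out for the averaged effect after its values were seen.

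Among male libraries, Xist was at 16.9 CPM in Cre male library 2 and 9.71 in stressed male library 1, against 1.11 to 7.26 in the other 10. The Y-linked Uty was at 1.37 ± 0.46 CPM in wild-type females. In the wild-type experiment the first principal component, with 33.7% of the variance, put the 4 libraries of replicate 1 at -39.6, -27.6, -36 and -22.4 and the other 8 at -3.45 or above.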
